A study of Mus musculus with 15 samples.

How the data were processed

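Bulk RNA sequencing was done on adipocytes of the skin (intradermal adipocytes), which float after collagenase digestion of mouse dorsal skin. The 15 libraries fell into 4 groups by their labels: controls at postnatal day 23 (P23, n = 3), mice with 2 days of Wnt activation at P23 (n = 4), controls at P26 (n = 3) and mice with 5 days of Wnt activation at P26 (n = 5). Activated β-catenin, the transcriptional effector of Wnt signalling, was switched on by doxycycline in the lineage of Engrailed-expressing cells (EngrailedCre; Rosa26rtTA; TetO-βcat). The labels give doxycycline in food (6 g/kg) and water (2 mg/mL) for all mice, controls included. Replicates are labelled as biological.

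The deposited table held raw counts per gene, one column per library, and these counts were used as the authors deposited them. The submitters' processing notes name Trimmomatic 0.39, SAMtools 1.9, Cufflinks 2.2.1 and DESeq2 1.40.1 and the mouse builds mm10 and GRCm38. The aligner, the counter and the use of strand are not given in the sources used here. Without the strand setting, genes that overlap an antisense gene and members of near-identical families are uncertain. Of 35373 genes in the table, 35300 had an identifier in the GENCODE M21 annotation of GRCm38, and 99.1% of those had the same chromosome, start and end, so coordinates below are those of the table. A filtered table of counts, also deposited by the authors, held 9395 genes, and a filter of at least 10 counts in every library applied to the raw counts gave the same number of genes. A further deposited table, with the same number of genes and the same library totals as the raw counts, was not used. The authors' deposited sample sheet gives a control group to the library labelled 2-day Wnt replicate 1, whereas its title and genotype give 2 days of Wnt activation. Its library name ends in C, as do the names of all controls, whereas the names of all other Wnt libraries end in W. It was kept in the group of its title.

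Total counts per library ran from 11383421 to 38501753, with 13027 to 16663 genes detected. Values of 1 or 2 made up only 0.946% to 1.94% of the nonzero values in a library, so 1 count need not stand for 1 molecule. Intervals, SEs and floors cover counting and replicate error as modelled only. A floor of 3 counts per library was used where all libraries of a group held 0 counts, and the fold over that floor is given. It is a lower bound only where zeros stand for a level under the floor.

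Genes were kept with edgeR's filterByExpr by group, which left 16935 genes and removed 18438. Library sizes were scaled with the trimmed mean of M values, and all 15 libraries were fitted with a 4-group model in edgeR's robust quasi-likelihood framework (edgeR 4.0.16, R 4.3.3). Contrasts were 2 days against P23 controls, 5 days against P26 controls, the difference between these effects, and P26 against P23 controls. P-values were two-sided and adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The SE of a log2 fold change was its size divided by the square root of the F statistic. Levels are given as CPM, the count of a gene relative to the normalized library size.

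Gene lists (25, of which 24 were tested and the sex-linked list served as a technical check) were written before the data were examined. They cover lipid and glucose metabolism, cholesterol synthesis, adipocyte identity, thermogenesis, Wnt targets and feedback inhibitors, extracellular matrix, proliferation, inflammatory mediators, the unfolded protein response, immediate early genes, mitochondrially encoded transcripts, and markers of stromal, keratinocyte, hair follicle, sebaceous, leukocyte, endothelial and mural, skeletal muscle, Schwann and erythroid cells. Elovl3 stands in both the thermogenic and sebaceous lists and Dpp4 marks stromal cells and is named on its own. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with adjustment over the 24 lists of a comparison. The same test with an estimated correlation and fry were alternatives fixed beforehand. The estimated correlation had a median of 0.48 over the lists, far above the preset value. A list score is the mean log2 CPM of its members in a library.

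Named genes were chosen by a rule fixed before the data were examined. It takes the 10 highest and 10 lowest log2 fold changes among called genes with a mean log2 CPM of at least 1 and every library on the same side of the control mean, up to 4 called members per list, and 15 genes always reported. For the difference and the control comparison it takes 5 in each direction and up to 2 per list. Where fewer than 5 genes passed in a direction, the 5 with the smallest p that met the other conditions are given as values. Predicted genes, Rik clones, mitochondrial, microRNA, ribosomal protein and sex-linked genes were not eligible.

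Alternatives fixed before the data were examined were other size factors, no filter, a filter of CPM above 5 in at least 3 libraries, DESeq2 1.42.0, fits of the compared groups alone, a fit without robust estimation, the replicate number as a block, a covariate for Y-linked transcripts (Ddx3y, Kdm5d, Eif2s3y and Uty summed), pooled controls and leaving out each library. An analysis of normalized values was foreseen only for the case that no counts existed and was not run. After seeing the data, these were added: limma-voom with library weights (voomWithQualityWeights), alone and with the covariate or with a library left out, the grouping of the authors' sample sheet, the authors' filter, leaving out both doubtful libraries together, and exact permutation of list scores. The rule for named genes was also applied to the weighted fit. The scripts were tested on simulated counts with 200 changed genes per comparison at the estimated dispersions. For the 5-day comparison (16090 simulated genes passed the filter), edgeR recovered 80.3% of 16-fold, 22.4% of 4-fold and 1.49% of 2-fold changes with 1 false call, and the weighted fit recovered 60.6%, 17.9% and 1.49% with 3 false calls. For the 2-day comparison (16012 genes), edgeR recovered 74.2%, 20.9% and 1.49%. The simulated counts were independent around a common mean profile, without outlier libraries or differences in sex or cell content. Their false calls therefore do not describe the error rate in these libraries.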

Results

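The RNA content of intradermal adipocytes was measured in 15 libraries from mice without and with β-catenin activation. Total counts ranged from 29441672 to 32617857 in the P23 controls (n = 3) and from 17270221 to 26945774 at 2 days of Wnt activation (n = 4). They ranged from 15700686 to 30799583 in the P26 controls (n = 3) and from 11383421 to 38501753 at 5 days (n = 5). Adipocyte genes were abundant in most libraries. Adipoq, which encodes adiponectin, stood at 1404 to 5259 CPM in 13 of the libraries, and at 370 CPM in P26 control replicate 1 and 722 CPM in 5-day replicate 5. Fasn (ENSMUSG00000025153, GRCm38 chromosome 11, 120805846 to 120824547, minus strand), which encodes fatty acid synthase, reached 40120 CPM in P23 control replicate 2.

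The libraries differed in ways that the groups do not describe. Xist, transcribed from the inactive X chromosome, was at 0 CPM in 8 of the 9 Wnt libraries and in 2 of the 6 controls (P23 control replicate 1 and P26 control replicate 1), and these 10 libraries held 44.8 to 149.8 CPM of Y-linked transcripts. The remaining libraries held Xist at 11.3 to 74.0 CPM and at most 1.39 CPM of Y-linked transcripts. P26 control replicate 1 held Krt14, a basal keratinocyte keratin, at 1054 CPM against 79.3 and 128.4 CPM in the other P26 controls, and it had the lowest library weight, 0.174. The library labelled 2-day Wnt replicate 1 held Krt25, a hair follicle keratin, at 1040 CPM against 0 to 6.07 CPM in the other 2-day libraries. Of its counts 31.7% were mitochondrial, against 8.37% to 19.4% in those libraries. The authors' sample sheet lists this library as a control. Krt14 and Krt25 were singled out from their lists after their values were seen.

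Axin2 (ENSMUSG00000000142, chromosome 11, 108920349 to 108950783, plus strand), a feedback inhibitor and widely used readout of Wnt/β-catenin signalling, served as the check of the activation. At P23 it stood at 39.8, 8.36 and 5.48 CPM in the controls and at 27.6, 65.0 and 43.5 CPM in 2-day replicates 2 to 4, while the library labelled 2-day Wnt replicate 1 held 10.01 CPM. At P26 the controls held 34.8, 9.07 and 4.17 CPM and the 5-day libraries 28.2 to 62.8 CPM. The log2 fold change was 1.03 ± 0.74 (SE) at 2 days and 1.43 ± 0.73 at 5 days, with edgeR adjusted p of 1 and 0.708. Averaged over both ages, Axin2 was 1.60 higher on the log2 scale in the Wnt libraries (exact permutation within each age, two-sided p = 0.0214, chosen after seeing the data). Axin2 followed the Xist and Y-linked split in every library, including P23 and P26 control replicate 1 (39.8 and 34.8 CPM) and the library labelled 2-day Wnt replicate 1, whose group is in conflict. The difference therefore does not establish activation apart from sex, and an exchange of labels among these libraries was not tested. Ctnnb1, which encodes β-catenin, stood at 240.4 ± 64.0 CPM in P23 controls (SD, n = 3) and 283.4 ± 140.9 at 2 days (n = 4), and at 248.4 ± 88.5 in P26 controls (n = 3) and 328.5 ± 62.0 at 5 days (n = 5).

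**Figure D1:**
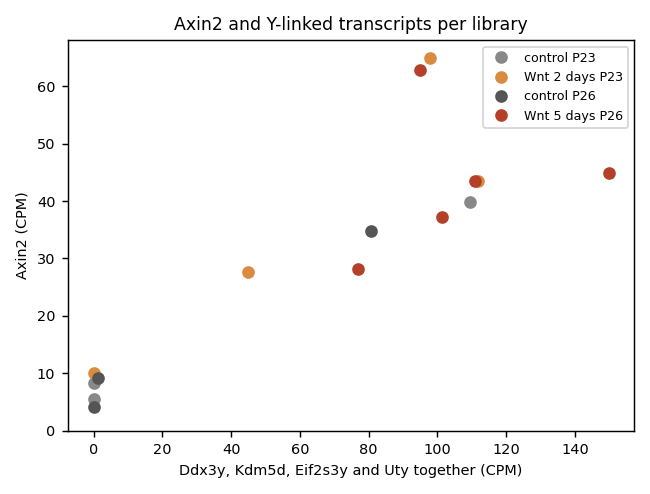
Axin2 (CPM) against the summed CPM of the Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty, one point per library, coloured by group. The libraries with at most 1.39 CPM of Y-linked transcripts held 4.17 to 10.01 CPM of Axin2, and the others 27.6 to 65.0 CPM.

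The comparison at 2 days asks what early Wnt activation does to adipocyte transcripts. All directions at 2 days include the library labelled 2-day Wnt replicate 1, whose title and sample sheet conflict. Genes of de novo lipogenesis, the making of fatty acids from acetyl-CoA, fell as a list: 16 of 17 members were lower, with a median log2 fold change of -1.20 (camera adjusted p = 2.76e-05; adjusted p = 0.608 with an estimated correlation). Lipolysis genes (11 of 11 lower, median -0.78, adjusted p = 0.00679), fatty acid oxidation (14 of 17 lower, median -0.37, adjusted p = 0.0218), lipid droplet and triglyceride synthesis (13 of 16 lower, median -0.67, adjusted p = 0.0296) and lipid and glucose uptake (10 of 13 lower, median -0.44, adjusted p = 0.0404) fell by the same test. Extracellular matrix genes rose (28 of 31 higher, median 0.89, adjusted p = 4.59e-07), as did Wnt targets and feedback genes (16 of 22 higher, median 0.56, adjusted p = 0.0104). With an estimated correlation no list passed, the adjusted p being 0.643, 0.701, 0.729, 0.635, 0.608 and 0.608 for these 6 lists in the order given.

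No single gene passed the threshold at 2 days. Fasn had a mean of 25680 ± 13470 CPM in controls (SD, n = 3) and 6775 ± 4279 at 2 days (n = 4), a log2 fold change of -1.92 ± 0.94 (SE, edgeR adjusted p = 0.919). Acaca, encoding acetyl-CoA carboxylase, stood at -1.54 ± 0.69, Srebf1, a regulator of lipogenic genes, at -1.11 ± 0.58, Scd1, a fatty acid desaturase, at -0.82 ± 0.82, the lipid droplet coat gene Plin1 at -0.79 ± 0.68 and the lipoprotein lipase gene Lpl at -0.83 ± 0.50. The adipogenic regulators Pparg and Cebpa stood at -0.41 ± 0.55 and -0.64 ± 0.63, and the adipokine genes Adipoq and Lep at -0.19 ± 0.68 and 0.31 ± 0.76. The adipocyte identity list was not called (13 of 18 lower, median -0.47, camera adjusted p = 0.205). The collagen gene Col1a1 stood at 0.99 ± 0.65, the Wnt effector Lef1 at 1.15 ± 1.44 and the stromal marker Dpp4 at 1.44 ± 0.68. The smallest p among eligible genes belonged to Plxdc2 (ENSMUSG00000026748, chromosome 2, 16356304 to 16755839, plus strand; 1.91 ± 0.42), Nbl1, an antagonist of bone morphogenetic proteins (1.84 ± 0.45), Olfml3 (1.88 ± 0.47), Ifi202b (2.65 ± 0.67) and Cerk (2.03 ± 0.54). The corresponding lower genes were Gbe1, the glycogen branching enzyme gene (-2.00 ± 0.45), Opa1, of mitochondrial fusion (-1.13 ± 0.32), the acute phase gene Saa1 (-5.00 ± 1.47), Sema4b (-1.48 ± 0.44) and Ncoa4 (-1.17 ± 0.36).

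Markers of other cells, and mitochondrially encoded transcripts as a measure of RNA quality and handling, moved with the 2-day group. Mitochondrial counts were 8.37% to 31.7% of the total at 2 days and 5.30% to 9.365% in P23 controls. Leukocyte markers (14 of 15 higher, median 1.16, camera adjusted p = 2.76e-05), stromal markers (11 of 12 higher, median 0.96, adjusted p = 0.00297), Schwann cell markers (7 of 7 higher, median 2.24, adjusted p = 0.0279) and mitochondrially encoded transcripts (9 of 9 higher, median 1.17, adjusted p = 1.51e-08) rose. Hair follicle genes also rose (9 of 9 higher, adjusted p = 0.000496), with a fitted median of 10.19, or 6.51 with the 4 genes at 0 in every library of a group placed at their bound. This rested on 1 library: the hair follicle score was 8.10 in the library labelled 2-day Wnt replicate 1 and -3.61, -1.70 and 1.37 in the others, against -2.49 to -1.97 in controls. With an estimated correlation the adjusted p was 0.608, 0.608, 0.623, 0.608 and 0.608 for these 5 lists. No single gene of 16935 passed in edgeR (smallest adjusted p = 0.919; 875 genes had an unadjusted p under 0.05, where chance gives 847), no member passed when adjusted over the list alone, and the weighted limma-voom fit called 0 genes. Adjusted over the list alone in the weighted fit, 3 mitochondrial, 3 stromal, 1 oxidation, 1 Wnt and 1 extracellular matrix gene passed. With weights the Schwann list lost its call (adjusted p = 0.197) and the erythroid list was called higher (adjusted p = 0.0182). DESeq2 called 156 (107 higher, 49 lower), of which 137 had 0 counts in at least 1 library. Without the library labelled 2-day Wnt replicate 1, 6 lists were called instead of 12, with lipogenesis at adjusted p = 5.43e-05. Hair follicle, stromal and Schwann markers were among the lists that lost their calls, but not the only ones. With the grouping of the authors' sample sheet 2 were called, lipogenesis (adjusted p = 0.00273) and keratinocyte markers (adjusted p = 4.93e-06), and Wnt targets and extracellular matrix each stood at adjusted p = 0.0666.

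**Figure D2:**
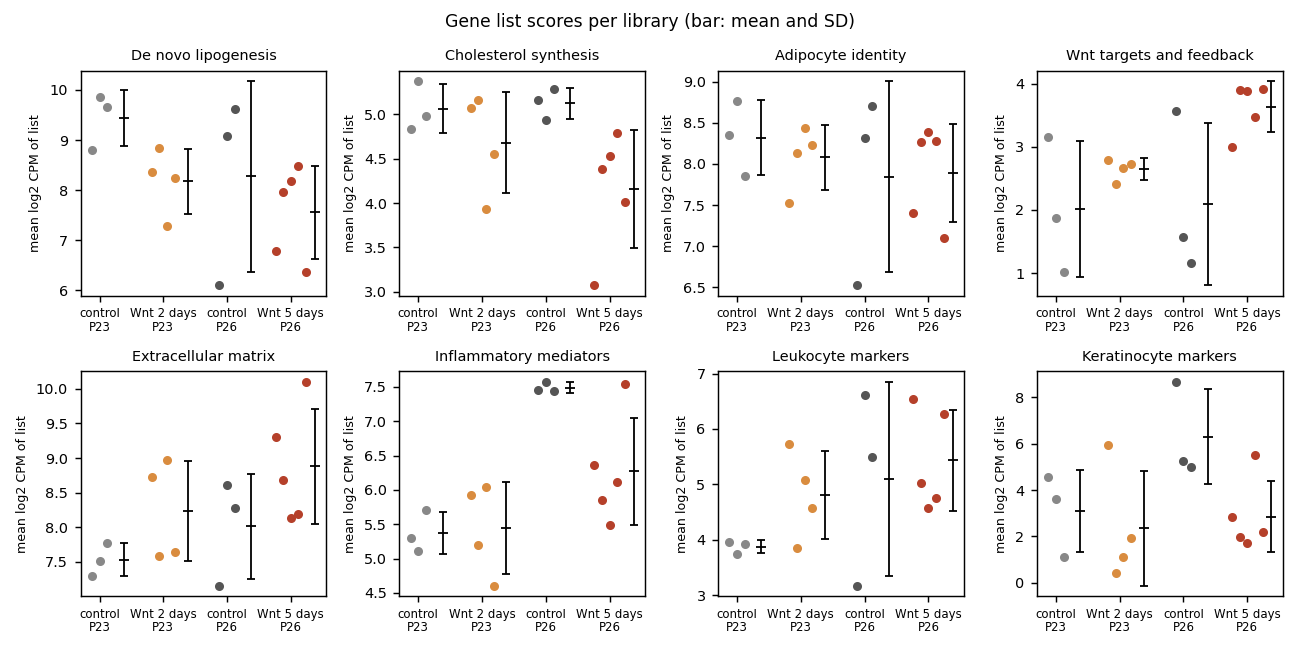
Scores of 8 gene lists (mean log2 CPM of the members) per library in the 4 groups, with one point per library and a bar for the group mean and SD. The lipogenesis score of P26 control replicate 1, 6.10, lies below those of the other P26 controls, 9.09 and 9.63, and all 3 P26 controls have an inflammatory score between 7.44 and 7.58.

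The comparison at 5 days asks which changes are present after longer activation. Wnt targets and feedback genes rose as a list (15 of 22 higher, median 0.32, camera adjusted p = 5.94e-05; adjusted p = 0.241 with an estimated correlation). Lipogenesis genes fell (16 of 17 lower, median -1.11, adjusted p = 0.0111; adjusted p = 0.748 with an estimated correlation), and so did the cholesterol synthesis genes (19 of 19 lower, median -0.79, adjusted p = 3.68e-07; adjusted p = 0.233 with an estimated correlation). Inflammatory mediators fell (13 of 14 lower, median -1.03, adjusted p = 1.02e-07; adjusted p = 0.233 with an estimated correlation), as did genes of the unfolded protein response (10 of 12 lower, median -0.53, adjusted p = 0.00125; adjusted p = 0.233 with an estimated correlation). Extracellular matrix genes rose (27 of 31 higher, median 0.93, adjusted p = 0.000109; adjusted p = 0.625 with an estimated correlation), but not in the weighted limma-voom fit (camera adjusted p = 0.859).

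In edgeR no gene passed at 5 days (smallest adjusted p = 0.166; 1195 genes had an unadjusted p under 0.05). The weighted limma-voom fit, chosen after seeing the data, called 226 genes, 34 higher and 192 lower, and DESeq2 called 227, 172 higher and 55 lower. All 5-day libraries held Y-linked transcripts, and the only P26 control that did had the weight of 0.174. With the Y-linked covariate the weighted calls numbered 133 (30 higher, 103 lower), so they are not separated from sex. Among the genes called in the weighted fit, Nkd2, a Wnt feedback inhibitor (ENSMUSG00000021567, chromosome 13, 73818534 to 73847631, minus strand), rose with a weighted log2 fold change of 4.65, against 1.38 ± 0.99 in edgeR (adjusted p = 0.851). Its CPM was 49.4, 1.95 and 0.852 in the P26 controls and 32.99 to 62.6 in the 5-day libraries. The Wnt targets Ccnd1, encoding cyclin D1, and Ccn4 also rose in that fit, Ccnd1 by 1.75 against 0.30 ± 0.59 in edgeR. P26 control replicate 1 held Ccnd1 at 89.05 CPM, above every 5-day library (34.2 to 56.3 CPM). The other P26 controls held 12.8 and 10.2 CPM. Ccn4 was at 0 counts in all 3 controls, and its mean in the 5-day libraries was 29.1-fold the floor of 3 counts per library. At 2 days Ccn4 went the other way, with 1.16, 1.56 and 0 CPM in P23 controls and 0 in all 2-day libraries, the library labelled 2-day Wnt replicate 1 with its conflicting group included. Gap43, a growth-associated neuronal gene, rose by 3.96, Kcne4, a potassium channel subunit, by 3.47, Tmem263 by 2.10, Nrep by 1.84, Lix1l by 1.73 and Dpysl3 by 1.73 on the weighted log2 scale. In edgeR these 6 stood at 4.15 ± 0.91, 2.58 ± 0.75, 2.14 ± 0.48, 2.25 ± 0.45, 1.47 ± 0.37 and 2.19 ± 0.50. Zfp30 and Fam174b rose by 6.09 and 5.90 in that fit but stood at 2.61 ± 1.35 and 1.52 ± 1.16 in edgeR (adjusted p = 0.708 and 0.875). Fam174b was 7.70 CPM in P26 control replicate 1, within the 5-day range of 5.40 to 11.2. Dcbld1 was at 0 counts in all 3 P26 controls, and its 5-day mean was 40.1-fold the floor. It stood at 4.04 CPM in P23 controls and 4.79 CPM at 2 days. Of the genes with a mean of at least 1 CPM, 16.1%, 3.35% and 6.15% were at 0 in these P26 controls. Zeros there need not mean absence, so neither fold over the floor is a sure lower bound.

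Genes that fell in the weighted fit included Pnpla3, a lipogenic target encoding a lipid droplet protein (197.2 ± 165.0 CPM in controls, n = 3, SD, and 33.7 ± 19.5 at 5 days, n = 5; weighted log2 fold change -2.51, edgeR -2.55 ± 0.76 with adjusted p = 0.613). P26 control replicate 1 held Pnpla3 at 6.89 CPM, below every 5-day library (12.9 to 52.4 CPM), so the fall rested on the other controls (286.0 and 298.8 CPM). Slc2a1, the glucose transporter GLUT1 gene, also fell (66.7 ± 26.8 and 17.8 ± 5.71 CPM; -1.38). The cytokine and chemokine genes Tnf (-3.17), Cxcl2 (-2.92), Il1b (-2.75), Cxcl10 (-1.71) and Ccl3 (-4.86) fell, with Il1rn, encoding the interleukin 1 receptor antagonist (-4.30). In edgeR these 6 stood at -1.43 ± 0.76, -1.49 ± 0.64, -1.31 ± 0.89, -1.45 ± 0.33, -2.18 ± 0.94 and -2.77 ± 1.06. In 5-day replicate 5 (weight 0.489) the inflammatory score was 7.54, within the control range of 7.44 to 7.58, and Il1b was 53.1 CPM, above all 3 controls (34.9 to 52.4 CPM). The macrophage-associated genes C1qa (-1.68), C1qb (-1.63), Fcer1g (-1.87) and Tyrobp (-1.51) fell in this fit, but were at -0.54 ± 0.54, -0.53 ± 0.57, -0.92 ± 0.60 and -0.61 ± 0.58 in edgeR. Krtdap, a keratinocyte differentiation gene (-6.52), Lypd5 (-5.76) and Hpx, encoding hemopexin (-4.04), also fell in the weighted fit, against -2.60 ± 1.89, -3.41 ± 1.62 and -3.64 ± 0.80 in edgeR. Krtdap was 58.5 CPM in 5-day replicate 4, above 43.6 and 51.9 CPM in P26 control replicates 2 and 3. Lypd5 was 19.9 CPM in that 5-day library, above 10.6 and 9.64 CPM in the same controls, and 142.9 CPM in P26 control replicate 1. Mup17, Mup16, Mup9, Mup10 and Mup14 (-4.83, -4.70, -4.40, -4.26 and -4.20) fell in the weighted fit, against -2.72 ± 1.23, -2.68 ± 1.22, -2.49 ± 1.00, -2.66 ± 1.03 and -2.53 ± 1.15 in edgeR. P26 control replicate 1 held Mup17 at 2.08 CPM, below every 5-day library (8.87 to 242.7 CPM), so the fall rested on the other controls. These genes are near-identical copies whose counts the counting could have split. Of the lists, 7 of 14 inflammatory mediators, 4 of 15 leukocyte markers and 1 of 17 lipogenesis genes were called lower and 3 of 22 Wnt genes higher in the weighted fit. The leukocyte list itself was not called at 5 days (10 of 15 lower, median -0.31, camera adjusted p = 0.986), and its score was 5.43 at 5 days against 5.09 in controls. That control mean rested on P26 control replicate 1, at 3.167 against 6.615 and 5.5 in the other P26 controls. The 5-day libraries ran from 4.58 to 6.547. Adjusted over the list alone, 10, 9, 5 and 13 members passed in the weighted fit and 1, 0, 0 and 0 in edgeR. By the same count 8 of 9 mitochondrially encoded and 7 of 12 keratinocyte members passed in the weighted fit. In edgeR 3 mitochondrially encoded, 3 cholesterol synthesis and 1 keratinocyte member passed.

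The genes reported in every case stood as follows at 5 days in edgeR, with none past the threshold. Fasn had a log2 fold change of -1.77 ± 0.87, Scd1 -1.23 ± 0.78, Acaca -0.92 ± 0.65, Plin1 -0.77 ± 0.65, Lep -0.73 ± 0.71, Lpl -0.46 ± 0.48 and Adipoq -0.39 ± 0.64. Srebf1 stood at -0.16 ± 0.56, Pparg at -0.15 ± 0.52, Cebpa at -0.13 ± 0.60 and Lef1 at -0.34 ± 1.33, while Dpp4 stood at 0.85 ± 0.64 and Col1a1 at 1.51 ± 0.65. The sign of Lef1 rested on P26 control replicate 1 (31.8 CPM against 0.594 and 0 in the other P26 controls) and turned to 4.79 without it. The smallest edgeR p among eligible genes belonged to Ldhb, a lactate dehydrogenase gene (ENSMUSG00000030246, chromosome 6, 142490249 to 142507957, minus strand; -2.53 ± 0.43, 76.5 ± 34.4 CPM in controls and 13.2 ± 2.37 at 5 days), Slc2a1 (-1.90 ± 0.36), the galectin 3 gene Lgals3 (-2.80 ± 0.53), the cell cycle inhibitor gene Cdkn1a (-1.68 ± 0.34) and Atrip (-1.35 ± 0.29) on the lower side. On the higher side were Dcbld1, Lrrc17 (1.88 ± 0.37), Nrep (2.25 ± 0.45), Gap43 (4.15 ± 0.91) and Clip3 (1.57 ± 0.35). Atrip wholly contains the gene Trex1 on the same strand. The P26 controls held Atrip at 136.3, 78.73 and 135.6 CPM and Trex1 at 129, 76.35 and 128.5 CPM. The fall of Atrip is therefore not told apart from a fall of Trex1. The falls of Lgals3, Cdkn1a and Atrip were set against P26 controls (means 421.1, 288.7 and 116.9 CPM) that lay above P23 controls (96.9, 137.9 and 38.8 CPM). The 5-day means were 60.6, 90.3 and 45.9 CPM, so Atrip at 5 days was not below its P23 control mean. Ldhb and Slc2a1 were also lower in P23 controls (36.5 and 36.3 CPM) than in P26 controls.

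**Figure D3:**
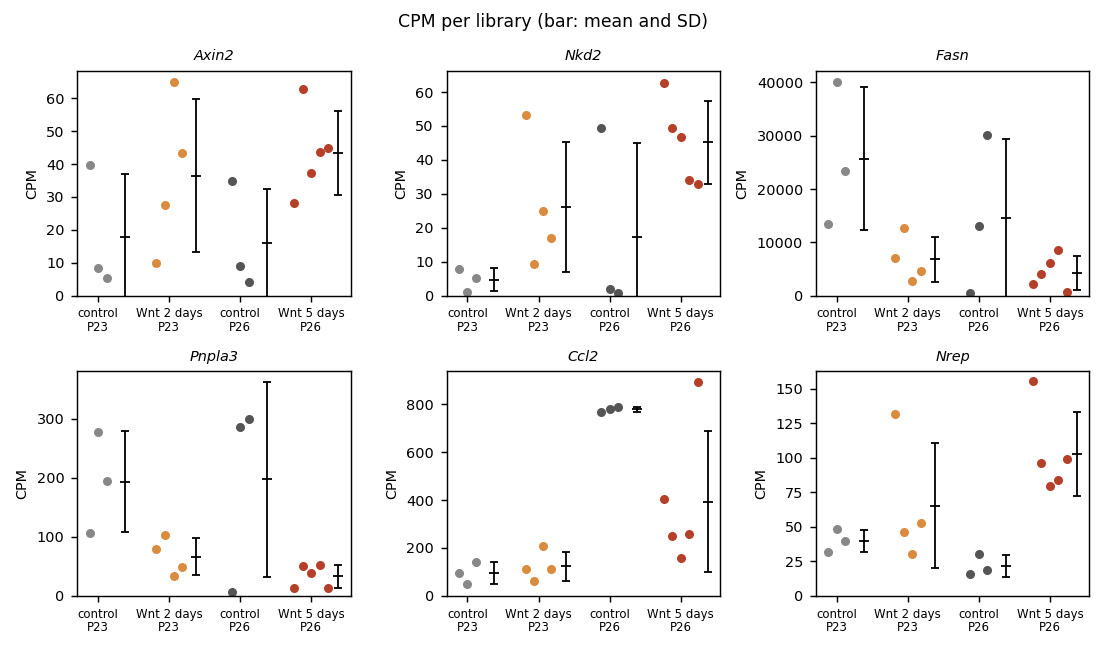
CPM per library of Axin2, Nkd2, Fasn, Pnpla3, Ccl2 and Nrep in the 4 groups, with one point per library and a bar for the group mean and SD. All 3 P26 controls hold Ccl2 between 766.7 and 787.6 CPM, and P23 controls between 51.5 and 141.2 CPM.

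Other-cell markers and mitochondrially encoded transcripts moved with the 5-day group as well. Mitochondrial counts were 9.20% to 16.6% of the total at 5 days and 3.69% to 7.93% in P26 controls. RNA quality or handling was therefore not separated from Wnt activation. Keratinocyte markers fell (12 of 12 lower, median -3.05, camera adjusted p = 1.02e-07; adjusted p = 0.241 with an estimated correlation). The size of that fall leaned on P26 control replicate 1, with a keratinocyte score of 8.663 against 5.251 and 4.983 in the other P26 controls. The score of 5-day replicate 4, 5.519, lay above those other controls. Mitochondrially encoded (9 of 9 higher, median 1.18, adjusted p = 3.68e-07), Schwann (7 of 7 higher, median 1.74, adjusted p = 0.0347) and erythroid transcripts (5 of 6 higher, median 1.44, adjusted p = 0.00892) rose. With an estimated correlation these 3 stood at adjusted p = 0.268, 0.589 and 0.488. With weights the Schwann and erythroid lists lost their calls (adjusted p = 0.0856 and 0.0678). Triglyceride synthesis (adjusted p = 0.0109), skeletal muscle (0.00225) and leukocyte markers (2.64e-08) were then called lower and hair follicle genes higher (0.0107). Without P26 control replicate 1, edgeR called 2 genes, Dusp10 (-1.97), a MAP kinase phosphatase gene, and Orm1 (-2.34), an acute phase gene, both named after their values were seen. The weighted fit then called 360 genes, and 17 lists were called instead of 10. In that setting the Wnt list had a median of 2.36 (adjusted p = 6.39e-11), lipogenesis -1.64 (adjusted p = 1.14e-09) and adipocyte identity -0.60 (adjusted p = 0.00381), while extracellular matrix lost its call (adjusted p = 0.0622). With the Y-linked covariate, the lipogenesis list at 5 days was not called (adjusted p = 0.866), nor were the Wnt targets (adjusted p = 0.0759), while lipogenesis at 2 days stood at adjusted p = 0.0447.

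The difference between the 5-day and 2-day effects was tested directly. It too includes the library labelled 2-day Wnt replicate 1, listed as a control in the sample sheet. Inflammatory mediators (12 of 14 lower, median -1.15, camera adjusted p = 3.09e-06), keratinocyte markers (12 of 12 lower, median -3.76, adjusted p = 0.000247) and cholesterol synthesis (16 of 19 lower, median -0.66, adjusted p = 0.00926) had a lower effect at 5 days. So did leukocyte markers (12 of 15 lower, adjusted p = 0.0104), skeletal muscle markers (12 of 12 lower, adjusted p = 0.0113) and hair follicle genes (9 of 9 lower, adjusted p = 0.0364). With an estimated correlation these 6 lists stood at adjusted p = 0.772, 0.772, 0.772, 0.974, 0.974 and 0.974. Lipogenesis was not called (adjusted p = 0.522). Wnt targets were not called either (adjusted p = 0.289), but had a higher effect at 5 days with library weights (camera adjusted p = 0.00273). With weights extracellular matrix (adjusted p = 1.42e-05) and stromal markers (0.0079) were also called with a lower effect, while cholesterol synthesis (0.160), keratinocyte (0.173) and hair follicle genes (0.976) lost their calls. Genes with the smallest p were Dcbld1, Tmem263 (2.65 ± 0.65), Gap43 (4.35 ± 1.13), Fer (2.30 ± 0.60) and B3gat2 (1.73 ± 0.49) with a higher effect. With a lower effect they were Ezr (-3.63 ± 0.87), Lsr (-5.37 ± 1.39), Stard10 (-3.39 ± 0.88), Gch1 (-3.20 ± 0.84) and Cdkn1a (-1.92 ± 0.51). P26 control replicate 1 held Ezr, Lsr, Stard10 and Gch1 at 342.8, 98.97, 111.5 and 96.93 CPM. The other P26 controls held at most 65.33, 9.462, 45.43 and 37.36 CPM, so the size of these effects leaned on replicate 1. For Lsr the 5-day libraries (2.79 to 15.7 CPM) spanned those other controls. The library labelled 2-day Wnt replicate 1 held Lsr at 38.4 CPM, against 2.96 to 13.4 in the other 2-day libraries. No gene passed in edgeR (smallest adjusted p = 0.810; 969 with an unadjusted p under 0.05) or in the weighted fit, and DESeq2 called 171. Across the 16935 genes, the log2 fold changes at 2 and 5 days correlated with a Pearson r of 0.0237 and a Spearman rho of 0.0718, a description across genes, which are not independent. For the 4430 genes with a mean log2 CPM of at least 5, these were 0.280 and 0.199. No gene was called at both times in edgeR, and in DESeq2 27 genes were called higher at both times, where independent lists would share 1.06 (Fisher's exact test, one-sided p = 6.85e-31), and 0 were called lower at both. Of the DESeq2 calls at 2 and 5 days, 87.8% and 59.0% had a library at 0 counts. With the authors' filter DESeq2 called 8 and 44 genes higher and shared 0.

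The controls themselves differed between P26 and P23, which matters because P26 controls are the reference at 5 days. The same P26 libraries enter these comparisons with opposite sign, so opposite changes in them are not independent. Whether age or the day of harvest lies behind the difference between controls was not tested. Inflammatory mediators rose (13 of 14 higher, median 2.48, camera adjusted p = 1.62e-13; adjusted p = 0.110 with an estimated correlation; fry adjusted p = 0.0212). Ccl2, a monocyte chemokine (ENSMUSG00000035385, chromosome 11, 82035571 to 82037453, plus strand), stood at 96.4 ± 44.9 CPM at P23 and 778 ± 10.6 at P26 (SD, n = 3 each), with a weighted log2 fold change of 3.02, called in the weighted limma-voom fit. Ccl7 (2.48), Ccl3 (4.76), Nlrp3, an inflammasome sensor (5.89), Oasl1 (5.19), Il1rn (4.89) and Hal (4.58) rose in that fit, as did the complement genes C1qb (2.60) and C1qc (2.44) and the stromal markers Thy1 (1.64) and Clec3b (2.16). In edgeR these 10 stood between 1.25 ± 0.45 (Thy1) and 4.86 ± 1.41 (Il1rn), none past the threshold. P26 control replicate 1 held C1qb, C1qc and Thy1 at 55.2, 64.3 and 78.5 CPM. These lay within the P23 control ranges of 46.0 to 59.9, 43.3 to 66.0 and 44.9 to 85.1 CPM, so the 3 rises rested on P26 control replicates 2 and 3. Ces1f, a carboxylesterase gene (-3.50), and Sfxn1, a mitochondrial serine carrier gene (-1.91), fell. Dcbld1 was at 0 counts in all P26 controls, with a P23 mean 32.8-fold the floor.

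Leukocyte (15 of 15 higher, median 2.11, or 1.99 with a gene at its bound), keratinocyte (12 of 12 higher, median 3.59), stromal (10 of 12 higher, median 1.09), extracellular matrix (26 of 31 higher, median 0.62) and hair follicle lists (9 of 9 higher, median 7.74, or 6.63 with 4 genes at their bound) rose between controls, with camera adjusted p of 3.79e-06, 3.79e-06, 0.00157, 0.00391 and 0.0304. The hair follicle rise rested on P26 control replicate 1, with a score of 6.26 against -2.86 and -2.66 in the other P26 controls. The keratinocyte score was 8.663 in that replicate, 5.251 and 4.983 in the other P26 controls and 1.123 to 4.549 in P23 controls. The leukocyte rise rested on those other P26 controls, at 6.615 and 5.5. Replicate 1 had a leukocyte score of 3.167, below the P23 controls (3.738 to 3.963). The lipogenesis (14 of 17 lower, median -0.82), triglyceride (14 of 16 lower), lipolysis (10 of 11 lower), oxidation (15 of 17 lower), uptake (11 of 13 lower), identity (14 of 18 lower), mitochondrial (9 of 9 lower) and erythroid (5 of 6 lower) lists fell, with adjusted p between 0.000532 and 0.0424. With an estimated correlation, the adjusted p of all of these was at least 0.537. In edgeR no gene passed (smallest adjusted p = 0.149; 1182 with an unadjusted p under 0.05), the weighted fit called 138 (131 higher, 7 lower) and DESeq2 302. Adjusted over the list alone, 9 of 14 inflammatory and 10 of 15 leukocyte members passed in edgeR, of 21 over all lists. The smallest edgeR p belonged to Ifi202b (4.14 ± 0.73), Pxdc1 (2.30 ± 0.42), Trex1 (2.01 ± 0.37), Ccl7 and Marcksl1 (3.14 ± 0.60) on the higher side and to Dcbld1, Ces1f, Sfxn1, Gap43 (-3.28 ± 0.91) and Septin6 (-1.60 ± 0.45) on the lower. Without P26 control replicate 1, the lipogenesis and identity lists lost their calls (adjusted p = 0.711 and 0.989), while inflammatory mediators stood at adjusted p = 3.03e-13. With weights the lipogenesis (0.586), triglyceride (0.190), uptake (0.140), identity (0.563), erythroid (0.407) and hair follicle lists (0.993) lost their calls by adjusted p. Immediate early genes (0.0329) and skeletal muscle markers (0.000401) were then called higher.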

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

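The list tests by camera, the outlier screen and the counts of splits were fixed beforehand. The score permutations, the score model with the Y-linked level, the score comparisons of single libraries and everything with library weights were chosen after the results were seen. Of 78 values screened for a library far from its group, 5 stood out, where chance gives about 3.9. Pparg in the library labelled 2-day Wnt replicate 1 was 6.87 log2 CPM, below 7.76 to 7.87 in the other 2-day libraries. In the same library the unfolded protein response score was 5.45, against 6.20 to 6.31, and the skeletal muscle score was 6.18, against 3.81 to 4.08. The endothelial and mural score was -0.096 in 2-day replicate 4, against 5.53 to 6.66, and 6.67 in 5-day replicate 5, against 5.26 to 5.65. The effects at 5 and 2 days differed by camera for inflammatory mediators (adjusted p = 3.09e-06), keratinocyte markers (0.000247), cholesterol synthesis (0.00926), leukocyte markers (0.0104), skeletal muscle (0.0113) and hair follicle genes (0.0364). None of these 6 passed with an estimated correlation (adjusted p = 0.772 to 0.974).

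The lipogenesis list was lower in Wnt libraries at both times. A smaller share of adipocyte RNA would lower both lipogenesis and adipocyte identity genes. The lipogenesis score minus the identity score was 0.893 lower in Wnt libraries averaged over both ages (a difference of -0.893, exact permutation within each age, p = 0.0235). The test includes the library labelled 2-day Wnt replicate 1. Whether other cells express the identity genes, which would lessen their fall, was not tested, so a smaller adipocyte share stays open. The unequal sex of the animals stays open: the Wnt effect on the lipogenesis score was -0.978 ± 0.546 (SE) without the Y-linked level in the model and -0.323 ± 0.579 with it, beside a Y-linked slope of -0.114 ± 0.055. The effect shrank to within its SE, and sex and Wnt activation cannot be told apart because 8 of the 9 Wnt libraries and 2 of the 6 controls held Y-linked transcripts. Wnt activation itself remains an untested explanation that the design names.

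The library labelled 2-day Wnt replicate 1 held little Axin2, and the authors' sample sheet calls it a control. A wrong label could not be decided from its Wnt target score. That score was 2.79, near 2.41 to 2.73 in the other 2-day libraries, but the P23 controls spanned 1.02 to 3.15. Its library name ends in C, as do those of all controls, whereas all other Wnt library names end in W. The name and the sample sheet point to a control, the title and genotype to 2 days of Wnt activation. RNA of hair follicle cells in place of adipocyte RNA is a candidate explanation for why it stood apart: its hair follicle score was 8.10, against at most 1.37 in the other 2-day libraries, and its adipocyte identity score was 7.52, below their 8.13 to 8.44. Such RNA need not come with low Axin2. P26 control replicate 1 had a hair follicle score of 6.257 and an adipocyte identity score of 6.524, but held Axin2 at 34.8 CPM. The label and the other-cell RNA can both hold.

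Inflammatory mediators were lower at 5 days than in P26 controls. A raised level in the P26 controls may account for it, since the 5-day libraries lay 0.905 above the P23 controls in list score (exact permutation p = 0.107), not below them. Fewer leukocytes in the Wnt libraries cannot be told apart at this sample size: the inflammatory minus leukocyte score was lower by 1.56 (a difference of -1.56) with exact permutation p = 0.0536. That difference leaned on P26 control replicate 1, with an inflammatory score of 7.457 beside a leukocyte score of 3.167. The leukocyte score itself was 5.43 at 5 days and 5.09 in P26 controls, and its list was not called (camera adjusted p = 0.986) but fell with library weights (camera adjusted p = 2.64e-08). The control mean rested on the same replicate 1, since the other P26 controls scored 6.615 and 5.5. Age and Wnt activation both stay open as biological explanations. All 5-day libraries held Y-linked transcripts, while P26 control replicates 2 and 3 held at most 1.39 CPM, so sex is not told apart either. A difference in handling or day of harvest between the groups was not tested.

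Other splits of the same libraries were counted for each result. For edgeR's 0 genes every split gives at least as many by construction (35 of 35 at 2 days, 56 of 56 at 5 days, 100 of 100 drawn for the difference and 10 of 10 for the controls), so these counts test nothing. The highest other counts were 1, 183, 202 and 0. The 183 genes came from setting P26 control replicate 1 and 5-day replicates 1 and 5 against the rest, the libraries with the lowest adipocyte identity scores at P26 (6.52, 7.41 and 7.10), which points to a structure of the samples. For called lists, 6 of 35 splits at 2 days (real 12, highest other 14), 22 of 56 at 5 days (real 10, highest other 16) and 73 of 100 for the difference (real 6, highest other 16) gave as many, so chance is not excluded. The other splits called a median of 6.5, 8 and 8 lists, the last above the real count. Camera's adjusted p at the preset correlation therefore cannot be taken at face value in these libraries. For the weighted fit at 5 days, 2 of 56 splits gave 226 genes or more. That fit was chosen after edgeR had called 0 genes, so this share does not exclude chance. The other split gave 992, the highest other count. It set P26 control replicates 2 and 3 with 5-day replicate 5 against the rest, which also points to a structure. The 10 splits of the controls are too few for a share under 0.05: 1 split, the real one, gave 14 lists or more (highest other 11, median of the others 9), and 1, the real one, gave 138 weighted calls (highest other 0).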

How the results depend on the processing

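Alternatives with library weights, the authors' filter, the authors' sheet, both doubtful libraries left out, and score permutation were chosen after seeing the data; the cause of each change was not tested unless stated. edgeR's count of 0 genes held in each comparison with other size factors, no filter, the strict filter and no robust estimation. It also held at 2 days, at 5 days and between controls with the compared groups alone, which was not run for the difference. DESeq2 called 156 genes at 2 days, 227 at 5 days, 171 for the difference and 302 between controls, with 27 shared by both times; of these calls 87.8%, 59.0%, 86.0% and 58.3% had a library at 0 counts. With the authors' filter, DESeq2 called 9, 79 and 135 genes at 2 days, at 5 days and between controls. Pooled controls gave 1 gene at 5 days (Lrrc17). With library weights 226 genes at 5 days and 138 between controls were called, 133 and 231 with the Y-linked covariate, and 360, 242 and, for the difference, 39 without P26 control replicate 1. Without both doubtful libraries edgeR called 4 genes at 5 days (Dusp10, Orm1 and Ldhb lower, Nkd2 higher).

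Whether replicate numbers pair the mice could not be told from the libraries. Same-numbered libraries correlated from -0.104 to 0.173 in their deviations (mean 0.0392, against -0.0103 for differently numbered pairs). Of the 15 libraries, 6 correlated best with their own number. With the replicate block, 5 genes were called between controls (Ifi202b, Marcksl1, Ccl2, Ccl7 and Ifit1, higher) and 0 in the other comparisons. Leaving out 1 library gave 0 genes at 2 days, 0 to 4 at 5 days, 0 to 2 for the difference and 0 to 2 between controls. The 4 at 5 days came without P26 control replicate 2 (Ldhb, Aldh1l2, Cplx2 and Gap43), which also gave the 2 for the difference and between controls (Aldh1l2 and Gap43). Called lists ranged from 6 to 14, 7 to 17, 3 to 7 and 8 to 14. The 6 at 2 days came without the library labelled 2-day replicate 1, the 17 and the 8 without P26 control replicate 1, and the 3 without P23 control replicate 1. Estimated correlation gave 0 lists in all 4 comparisons, fry 0, 0, 0 and 1, and score permutation 0 in the 3 it covers. The authors' sheet gave 2 lists at 2 days and 8 between controls. Leaving out both libraries gave 6, 17 and 7 lists at 2 days, 5 days and between controls, and weights without P26 control replicate 1 gave 9 between controls.

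Signs turned for these genes, all values log2. None was called in edgeR, but C1qa, C1qb, Tyrobp, Fcer1g and Ccnd1 were called at 5 days in the weighted fit. With the block at 5 days Lef1 was 2.94, Pparg 0.019, Cebpa 0.0049 and Srebf1 0.00014. With the Y-linked covariate at 5 days Pparg was 0.0526, Srebf1 0.31, Acaca 0.0867, Lep 0.18 and Tyrobp 0.0691. With pooled controls Ifi202b was -0.57 and Lep -0.39 at 2 days, and Lef1 0.12, C1qa 0.16, C1qb 0.21 and Tyrobp 0.0331 at 5 days. The inflammatory list then fell at 2 days (adjusted p = 0.000304) and the leukocyte list rose at 5 days (0.00301). With weights Lef1 was 5.36 at 5 days, 6.44 without P26 control replicate 1, and with the covariate -0.85 at 2 days and 3.33 at 5 days, beside Dpp4 -0.12, Srebf1 0.16 and Lep 0.17. Weights without P26 control replicate 1 turned extracellular matrix at 5 days (adjusted p = 0.930) and lipogenesis between controls (0.888). Weights without the library labelled 2-day replicate 1 gave Ctnnb1 -0.16 and Adipoq 0.17 at 2 days. By the authors' sheet Ctnnb1 was -0.48, Lef1 -0.19, Dpp4 -0.41 and Adipoq 0.31. Without both libraries Ctnnb1 was -0.16 and Adipoq 0.0621 at 2 days, Lef1 4.79 at 5 days, and adipocyte identity turned for the difference (adjusted p = 0.0453). Leaving out 1 library, Lep ranged from -0.33 to 0.79, Ctnnb1 from -0.16 to 0.44 and Adipoq from -0.44 to 0.0991 at 2 days. At 5 days Lef1 ranged from -0.93 to 4.79, Pparg from -0.61 to 0.23, Cebpa from -0.50 to 0.48 and Srebf1 from -0.58 to 0.44. Adipoq ranged from -0.90 to 0.30, Ccnd1 from -0.14 to 2.01 and Fcer1g from -1.40 to 0.13.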

Other observations

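Endothelial and mural, sebaceous, proliferation, thermogenic and immediate early lists were not called by camera on log2 CPM in any of the 4 comparisons. At 2 days the endothelial and mural list had a median log2 fold change of 0.50 (11 of 12 higher) while camera put it lower (adjusted p = 0.909), and the keratinocyte list had a median of 0.34 with the test on the lower side (adjusted p = 0.513). At 5 days the medians of thermogenic (-0.56, adjusted p = 0.744), proliferation (-0.04, adjusted p = 0.704), sebaceous (-1.44, adjusted p = 0.067), immediate early (-0.36, adjusted p = 0.168) and endothelial and mural genes (1.07, adjusted p = 0.216) did not pass. The 5-day hair follicle list had a median of -2.04 with the test on the higher side (adjusted p = 0.986), fatty acid oxidation -0.13 with the test on the higher side (adjusted p = 0.986), and uptake 0.01 with the test on the lower side (adjusted p = 0.0851). At 5 days, lipolysis (median -0.01, adjusted p = 0.730), triglyceride synthesis (-0.48, adjusted p = 0.0724), stromal (0.48, adjusted p = 0.217) and skeletal muscle genes (-1.01, adjusted p = 0.0521) were not called. With library weights triglyceride synthesis (0.0109) and skeletal muscle (0.00225) were called lower and hair follicle genes (0.0107) higher at 5 days, and immediate early genes (0.0329) higher between controls. For the difference between the 5-day and 2-day effects, which includes the library labelled 2-day Wnt replicate 1 with its conflicting group, the Wnt list had a median of -0.30 with the test on the higher side (adjusted p = 0.289). Between controls the cholesterol list had a median of -0.09 with the test on the higher side (adjusted p = 0.546).

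Averaged over both ages, the Wnt target score was 1.09 higher in Wnt libraries (exact permutation within each age, two-sided p = 0.0189), and the lipogenesis score -0.99 (p = 0.0888). Both tests were chosen after seeing the data, and both include the library labelled 2-day Wnt replicate 1 with its conflicting group. The controls with Y-linked transcripts, P23 and P26 control replicate 1, had Wnt target scores of 3.15 and 3.56, above all 2-day libraries (2.41 to 2.79). The library labelled 2-day Wnt replicate 1 and P26 control replicate 1 had the highest hair follicle scores (8.10 and 6.26). They also held the highest Lef1 (20.5 and 31.8 CPM) and Ccnd1 (81.1 and 89.05 CPM), genes picked from the list after their values were seen. Their Axin2 stood at 10.01 and 34.8 CPM. The Wnt target difference was not separated from sex, from RNA of hair follicle cells or from an exchange of labels.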
